A study of Rattus norvegicus and Mus musculus with 74 samples.

How the data were processed

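The data were ChIP-seq measurements of 4 histone marks in brain cortex of rats and mice. H3K4me3 marks active promoters, H3K9Ac is an acetylation of active promoters and enhancers, H3K27me3 is the Polycomb mark of repressed genes, and H3K9me3 is the mark of constitutive heterochromatin. Per the labels, Sprague-Dawley rats were either controls or had been exposed to valproate (VPA) before birth, and C57BL/6J mice were either controls or had been exposed before birth to poly I:C, a synthetic double-stranded RNA that sets off an antiviral response in the pregnant dam. Exposed animals received vehicle or TAK-418, an inhibitor of the histone demethylase LSD1 (gene Kdm1a); controls received vehicle. Each of the 3 groups of a species had 3 libraries per mark, which makes 72 ChIP libraries among 74 samples. The other 2 samples were 1 pooled input per species, whose signal was not used here. The labels do not say that the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may in part be technical.

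Per the labels' protocols, frozen cortex was fixed with formaldehyde, 30 ug of chromatin went into each immunoprecipitation and libraries were sequenced on an Illumina NextSeq instrument. Per the submitters' processing notes, reads were aligned with BWA 0.7.12 to the mm10 and rn5 genome builds. The peak caller, the width of the bins and the scaling between libraries are not given in the sources used here. Library names carry a tag that could stand for added fly chromatin, but no source states how it was used.

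The deposited values were signal over merged regions, 1 table per species, per the file headers: for each region and library a mean signal, a highest signal and whether an interval was called there. Mouse regions numbered 60110 (median length 6599 bp, longest 692399 bp) and rat regions 72824 (median 5199 bp, longest 423999 bp). The mean signal was 0 or at least 1 and had no read counts behind it in the tables, so the depth of a library is unknown and no counting interval was computed. The tables list genes with each region (23362 genes in mouse, 20110 in rat), their distance to the gene start and the CpG islands of the region. All columns of libraries were matched to a sample by name (0 were left unmatched). Coordinates are those of the tables, on mm10 or rn5. The reference table supplied for rat is of another assembly and was not used.

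A gene took the value of the region, among those listing it, with the highest mean over all libraries of its species; 12379 mouse and 12242 rat genes were listed with more than 1 region. Genes that share a region carry the same value, and the number of distinct regions is given beside counts of genes called as deposited. Members of a gene list, such as clustered genes, can share a region, which the list tests do not take into account. Genes were tested for a mark where an interval had been called in at least 3 of its 9 libraries; this filter was set after the tables had been seen. The test was limma with a mean-dependent prior and robust estimation on log2(mean signal + 1), the values as deposited, with 1 model per mark and species over 9 libraries and Benjamini-Hochberg adjustment at 0.05 within each comparison. A planned test for read counts was not used, since the values were signal. Fold changes are on the log2(signal + 1) scale, which understates the change of weakly marked genes. Each comparison was fitted again after subtracting each library's median over distinct regions (median centring) and after quantile normalization. Genes past the threshold under both rescalings are called relative changes; this pair of criteria was chosen after seeing the data. The comparisons were exposed vehicle against control, exposed TAK-418 against exposed vehicle, and exposed TAK-418 against control.

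The comparisons, the model, the rule for named genes, 34 gene lists and the alternatives were fixed before the data were examined, except where stated. The rule named, per comparison and scaling, the 10 genes with the largest increase and the 10 with the largest decrease among those past the threshold, without overlap between the groups and in the upper 75% by level. Unnamed gene models and pseudogenes were counted but passed over in naming. Where no gene passed, it named the 3 with the smallest p in each direction. It also named the 4 members of each list with the smallest p, Kdm1a in each H3K4me3 comparison, and 12 marker genes. Not all named genes are given in the text, and results of some are not reported here. Lists needed 5 tested regions and were compared with the other distinct tested regions by camera, with a preset inter-gene correlation of 0.01. The p-values were adjusted over the lists and marks of a comparison (99 in rat, 87 in mouse). The test was run again with the correlation estimated from the libraries. Higher or lower is the side camera gave, which in some lists was not that of the median log2 change. Lists covered brain cell types, synapses and receptors, chromatin enzymes, developmental regulators, gene families in heterochromatin, and housekeeping genes. The list of autism risk genes shares 3 genes with the synaptic list and 2 with that of LSD1 complex and H3K4 methylation enzymes.

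Summed signal was compared between groups with exact two-sided permutation tests, whose smallest possible p with 3 against 3 libraries is 0.1. The vehicle libraries enter both changes that a reversal compares, so the correlation and covariance of these changes across genes were set beside 100 simulations of unchanged groups. Model fits were tested on simulated data with 200 genes changed in each mark, 100 by 0.5 and 100 by 1 on the log2 scale, with noise of each gene's own spread. For vehicle against control, the rat fits recovered 58%, 60.0%, 8% and 73% of genes changed by 1 in H3K4me3, H3K9Ac, H3K27me3 and H3K9me3, and the mouse fits 46%, 70.0%, 22% and 2%. Of genes changed by 0.5, the rat fits recovered 1%, 3%, 0% and 24%, and the mouse fits 5%, 2%, 5% and 1%. Libraries were checked for copies: the replicate pairs of a group correlated between 0.112 and 0.973 across regions, at most 19.3% of regions were identical, and none was treated as a copy.

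Alternatives were the scalings, a fit without trend and robust estimation, other pseudocounts, no filter, the upper 50% of genes by level, the highest signal in place of the mean, other ways to assign a region to a gene, regions in place of genes, the 6 libraries of the groups compared, the replicate number as a block, and each library left out in turn. R 4.3.3 with limma 3.58.1 and the data.table package at 1.17.8, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.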

Results

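Signal of 4 histone marks was measured in cortex of control rats, VPA-exposed rats and such rats treated with TAK-418. Mouse groups were the same, with prenatal poly I:C. Each group held 3 libraries per mark. The design asks how prenatal exposure altered the marks and whether inhibition of LSD1, which removes methyl groups from H3K4, moved them toward or away from the control state. Read depth is unknown.

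In control cortex, the Polycomb mark H3K27me3 was highest over the genes of body patterning. The median Hox gene stood at percentile 99.6 ± 0.0478 of all genes in rats and 99.7 ± 0.00247 in mice (SD, n = 3 libraries), and other developmental transcription factors at 98.4 ± 0.225 and 98.7 ± 0.0601. Hoxd10 had a mean signal of 31.4 ± 12.8 in rats (percentile 99.9, chromosome 3, 68067000 to 68092799) and 17.0 ± 3.58 in mice (percentile 99.7). Hoxa9 had 19.9 ± 4.48 in mice, and Pax3, a neural crest and muscle regulator, 13.5 ± 4.50 and 10.8 ± 2.48. Neuronal identity genes were also high in this whole-tissue measurement: inhibitory neuron markers lay at 97.3 ± 0.094 in rats and 96.3 ± 0.847 in mice, and excitatory neuron markers at 90.6 ± 0.995 and 92.6 ± 0.764. Wnt ligand genes lay at 94.9 ± 0.227 and 95.6 ± 0.088, and neural progenitor genes at 93.2 ± 0.245 and 92.5 ± 0.829. Gad1, the enzyme that makes GABA, reached percentile 98.2 in rats and 97.2 in mice, and Slc17a7, the vesicular glutamate transporter of cortical neurons, 92.1 and 96.8. Striatum markers lay at 91.1 and 85.6, choroid plexus markers at 78.3 and 83.4, astrocyte markers at 78.1 in both and microglia markers at 66.3 and 82.1. Ribosomal protein genes lay near the middle, at 46.2 and 50.2.

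H3K9me3 was high over chemosensory receptor families that are clustered in heterochromatin. Olfactory receptor genes stood at percentile 85.1 ± 1.61 in rats and 88.5 ± 1.47 in mice (SD, n = 3), vomeronasal receptor genes at 89.1 ± 0.633 and 92.7 ± 1.23, imprinted genes at 85.5 ± 6.26 in rats but 62.1 in mice, and Hox genes at 73.8 ± 25.3 and 85.0 ± 0.738. The same olfactory receptor genes were near the bottom for H3K4me3 (9.14 and 7.23) and for H3K9Ac (7.11 and 7.07).

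The active marks H3K4me3 and H3K9Ac were high over housekeeping genes and chromatin regulators. Ribosomal protein genes lay at percentiles 66.9 ± 0.92 for H3K4me3 and 72.5 ± 0.266 for H3K9Ac in rats (SD, n = 3) and at 68.0 ± 1.54 and 77.4 ± 0.271 in mice. LSD1 complex and H3K4 methylation enzymes lay at 75.4 ± 2.83 and 82.3 ± 2.71 in rats and 74.5 ± 2.52 and 78.9 ± 3.15 in mice. Synaptic genes were at 60.0 ± 1.27 and 71.9 ± 3.27 in rats and 74.4 ± 0.546 and 78.9 ± 1.57 in mice. For H3K9Ac, circadian clock genes lay at 79.3 in rats and 84.1 in mice, autism risk genes at 69.9 and 72.3, glutamate receptor genes at 66.4 and 72.7, and clustered protocadherins at 51.4 and 90.7. Actb, the cytoskeletal actin, had an H3K9Ac signal of 14.7 ± 1.42 in rats (percentile 97.6) and 11.4 ± 2.65 in mice (percentile 94.7), and Snap25, a protein of synaptic vesicle fusion, 12.7 ± 0.551 and 8.32 ± 2.74. Hoxd10 had an H3K4me3 signal of 1.40 ± 0.202 in rats, at percentile 20.2, and the muscle myosin Myh4 1.30 ± 0.450 in mice, at percentile 6.92.

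**Figure D1:**
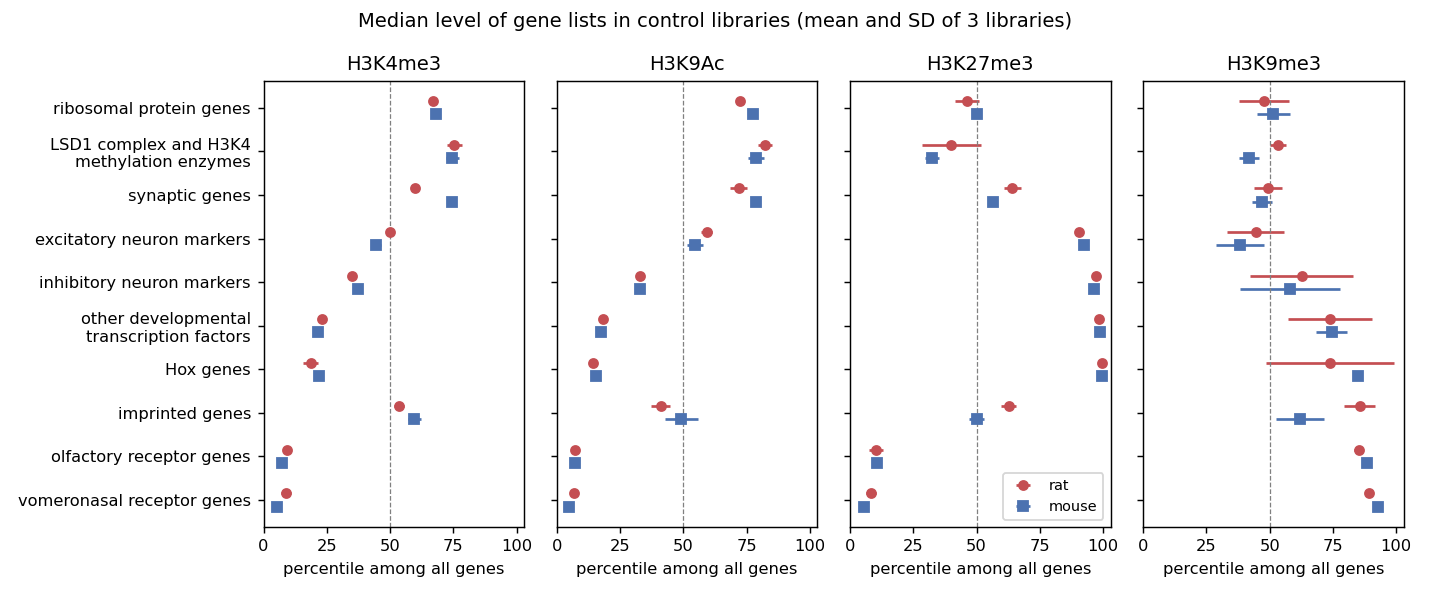
Percentile of the median gene of 10 gene lists (y axis) among all genes of the same library (x axis, percentile from 0 to 100) for each mark, in control rats (circles) and control mice (squares); points are means and bars the SD of 3 libraries. Hox genes lay at 99.6 in rats and 99.7 in mice for H3K27me3 and at 14.4 and 15.7 for H3K9Ac.

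The amount of H3K4me3 and H3K9Ac signal differed between groups of libraries, in opposite directions in the exposure models. Rat H3K9Ac summed to 117700 ± 11600 in controls, 236100 ± 65570 in VPA rats given vehicle and 154000 ± 24230 with TAK-418 (SD, n = 3). The ratio of vehicle to control was 2.01 (exact two-sided p = 0.1, the smallest that 3 against 3 libraries allow) and that of TAK-418 to vehicle 0.653 (exact p = 0.2). Rat H3K4me3 summed to 246200 ± 45290, 329600 ± 10910 and 388400 ± 79710. Its ratios were 1.34 (exact p = 0.1) for vehicle to control, 1.18 (exact p = 0.4) for TAK-418 to vehicle and 1.58 (exact p = 0.1) for TAK-418 to control. Rat H3K9me3 was 1.31 times control in vehicle and 1.32 times control with TAK-418 (exact p = 0.1 for both). Its called intervals numbered 13030 ± 4618, 25560 ± 2660 and 22210 ± 6696. In mice, H3K4me3 was 213000 ± 82670 in controls and 139500 ± 13750 in poly I:C vehicle libraries, a ratio of 0.655 (exact p = 0.1), and 150400 ± 12790 with TAK-418. Mouse H3K9Ac was 144500 ± 32300 in controls and 92730 ± 16470 in vehicle, a ratio of 0.642 (exact p = 0.1), and 94930 ± 16340 with TAK-418, 1.02 times vehicle (exact p = 0.8). Mouse H3K27me3 was 58350 ± 3506 with TAK-418 against 77280 ± 10030 in controls, a ratio of 0.755 (exact p = 0.1). Vehicle over control was 0.956 (exact p = 0.9) for rat H3K27me3, 1.08 (exact p = 0.8) for mouse H3K27me3 and 0.885 (exact p = 0.5) for mouse H3K9me3. The groups did not overlap in 5 of the 12 rat and 4 of the 12 mouse comparisons of this sum, where chance alone gives 10%.

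**Figure D2:**
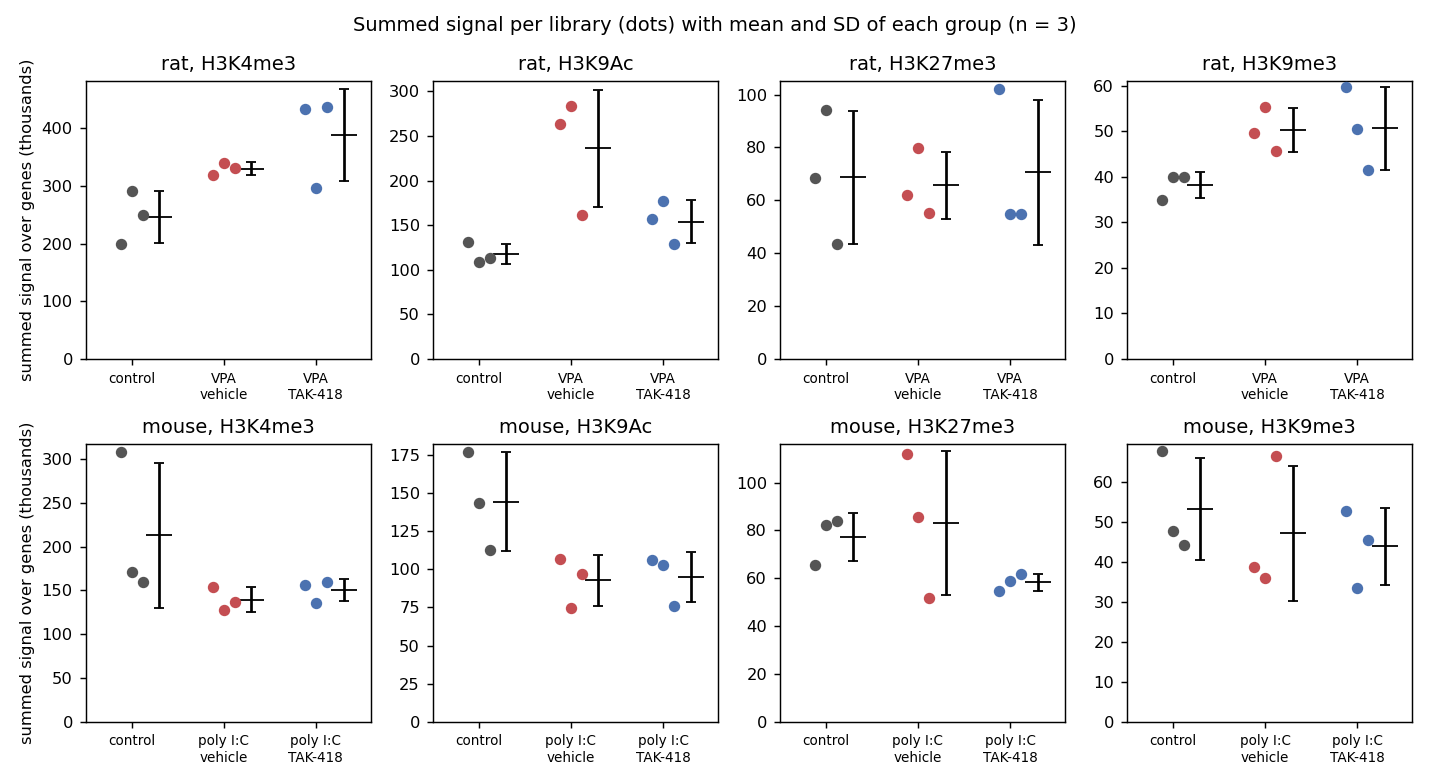
Signal summed over all genes (y axis, scaled as labelled) for each library (dots) by mark and species, with the mean and SD of each group (n = 3) beside them. The 3 rat H3K9Ac libraries of VPA vehicle lie between 161340 and 283850, above the highest control at 130930, and the mouse H3K4me3 control libraries include 1 at 308210 beside 171420 and 159370.

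Because these shifts touch nearly every gene, changes are given as deposited and again relative to the other genes. Scaling between libraries was not separated from exposure or treatment. In VPA rats given vehicle, the median log2 change over all tested genes was 0.41 for H3K4me3, 0.88 for H3K9Ac, 0.01 for H3K27me3 and 0.40 for H3K9me3. With TAK-418 against vehicle the rat medians were 0.21, -0.52, 0.06 and -0.04, and against control 0.61, 0.36, 0.06 and 0.36. In mice, the medians were -0.49, -0.56, 0.05 and -0.41 for vehicle against control, 0.13, 0.05, -0.46 and 0.17 for TAK-418 against vehicle, and -0.37, -0.53, -0.40 and -0.22 for TAK-418 against control. Median centring brought all of these medians to between -0.08 and 0.05.

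**Figure D3:**
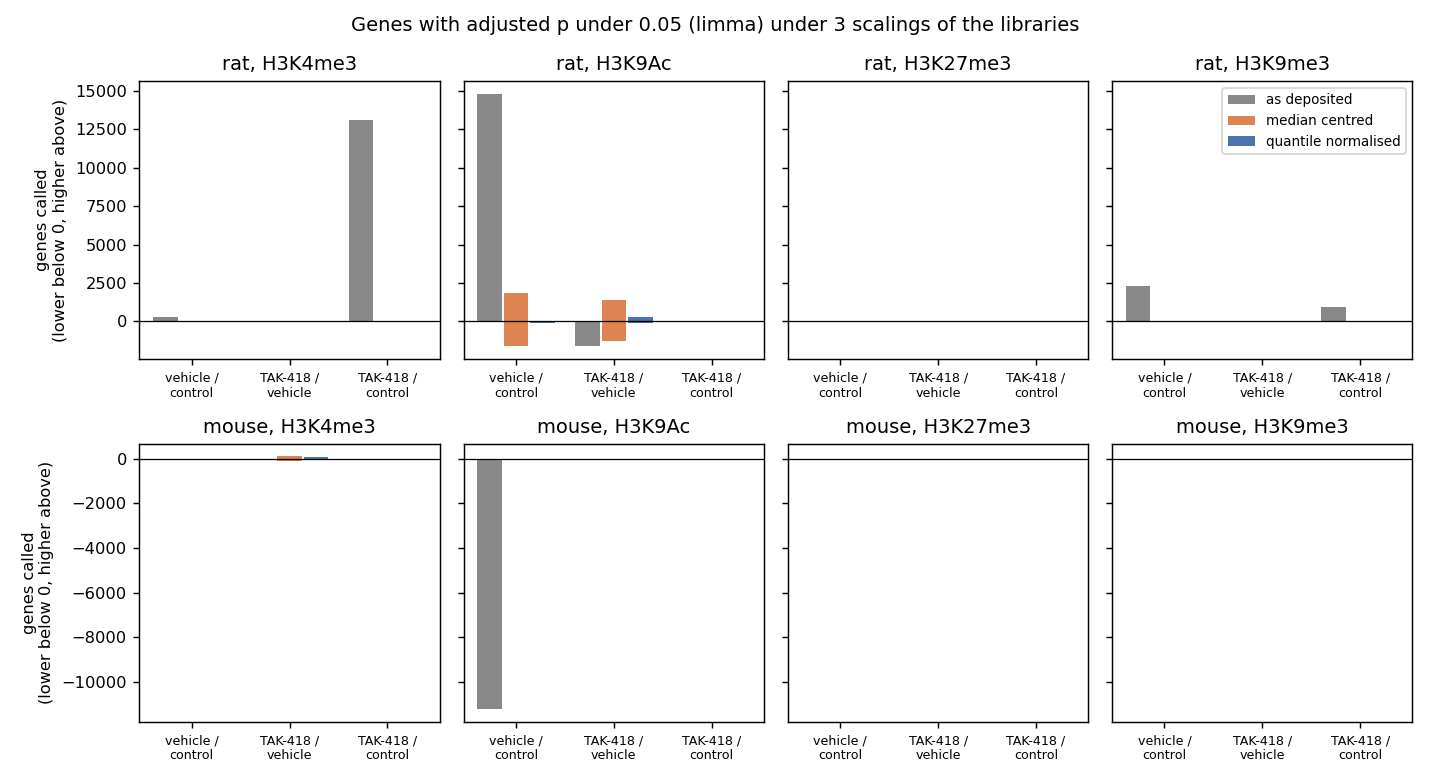
Genes past an adjusted p of 0.05 in limma (y axis, higher above 0 and lower below 0) in each comparison of each mark and species, for values as deposited, median centred and quantile normalized. In rat H3K9Ac, vehicle against control, 14835 genes as deposited became 3459 after median centring and 101 after quantile normalization.

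For H3K4me3 in rats, 250 of 15287 genes (204 regions) were called higher in VPA rats given vehicle than in controls as deposited and 0 lower, and 98.6% of genes had the higher mean in vehicle. Among the largest increases were Zbtb7c (41.5 ± 4.25 in vehicle against 20.4 ± 10.6 in controls, SD, n = 3; log2 change 1.09, SE 0.246, adjusted p = 0.00918, inside the gene at chromosome 18, 71256200 to 71256599) and the platelet growth factor Thpo (14.6 ± 1.02 against 7.12 ± 4.13; 1.07, SE 0.209, adjusted p = 0.00154). Rims2, a scaffold of the presynaptic release site, had 65.8 ± 4.88 against 35.1 ± 13.6 (0.95, SE 0.274, adjusted p = 0.0424, upstream at chromosome 7, 78155600 to 78161199). Kdm1a, the gene of LSD1, had 9.05 ± 2.55 in controls, 14.0 ± 0.902 in vehicle and 15.7 ± 4.03 with TAK-418. Neural progenitor genes did not pass as a list (adjusted p = 0.0768, 13 genes, median 0.54 against 0.41 for all). After median centring or quantile normalization limma called 0 genes (2002 and 1900 at unadjusted p under 0.05), and without the interval filter 2, both lower. Leaving out 1 library gave between 2 genes (without control 1) and 8365 (without control 2). It gave 7 without control 3, 4, 3 and 15 without vehicle 1, 2 and 3, and 104 and 8225 without TAK-418 libraries 1 and 2.

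In TAK-418 against vehicle, H3K4me3 was called higher at 21 rat genes (19 regions) and lower at 0 as deposited. Znrf4, the 1 gene that met the naming rule, had 23.2 ± 4.65 with TAK-418 and 12.3 ± 1.31 in vehicle (SD, n = 3; log2 change 0.84, SE 0.21, adjusted p = 0.0424; upstream at chromosome 9, 9524200 to 9533599). Limma called 0 genes after either rescaling (468 after median centring and 522 after quantile normalization at unadjusted p under 0.05). Leaving out 1 library gave between 0 (without vehicle 2) and 509 genes (without TAK-418 library 2). It gave 38, 53 and 12 without controls 1, 2 and 3, 1 and 9 without vehicle 1 and 3, and 1 (a lower gene) and 3 without TAK-418 libraries 1 and 3.

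Against control, TAK-418-treated VPA rats had higher H3K4me3 at 13112 genes and lower at 1 (8069 regions in all). This was Ccdc129 (4.63 ± 0.639 against 6.68 ± 2.45, log2 change -0.40, adjusted p = 0.0351), chosen after its values were seen. The largest increases were Tchh, the hair follicle protein trichohyalin (26.4 ± 10.1 against 8.05 ± 4.90, SD, n = 3; 1.65, SE 0.211, adjusted p = 3.27e-11), Sowahb (1.40), Zbtb7c (1.39), Znrf4 (1.33) and Pbx3 (1.32). The stress hormone releasing factor Crh had 18.7 ± 5.85 against 6.71 ± 0.737 (1.31, SE 0.206, adjusted p = 1.1e-07, upstream at chromosome 2, 124182400 to 124187799) and the activin antagonist Fst 19.5 ± 7.02 against 7.69 ± 3.00 (1.24, SE 0.209, adjusted p = 8.47e-07). Wnt ligand genes (all 13 higher, 13 adjusted over the list alone, median 0.69 against 0.61; adjusted p = 0.00532) and striatum markers (all 10 higher, 10 adjusted over the list alone, median 0.75; adjusted p = 0.0269) were called higher than the other genes, which neither was with an estimated correlation (adjusted p = 0.998). Camera also called other developmental transcription factors higher (40 of 40, 40 adjusted over the list alone, adjusted p = 0.00495, and 0.998 with an estimated correlation). Yet their increases were mostly smaller: the median was 0.53, and 13 lay above the 0.61 of all genes. After rescaling limma called 0 genes (2409 and 2421 at unadjusted p under 0.05). Without control 1, TAK-418 library 1 or TAK-418 library 3 the count was 5473, 3558 and 6451.

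For H3K9Ac in rats, 14835 of 15368 genes (9247 regions) were called higher in VPA rats given vehicle than in controls as deposited. Asb12 went from 8.77 ± 2.81 in controls to 31.3 ± 11.1 in vehicle (SD, n = 3; log2 change 1.70, SE 0.264, adjusted p = 1.94e-06, chromosome X, 65620400 to 65620799). Tab2, an adaptor of inflammatory kinase signalling, went from 29.4 ± 8.18 to 85.5 ± 16.7 (1.52, SE 0.281, adjusted p = 7.8e-05, chromosome 1, 3770000 to 3770599). Scap, a cholesterol-sensing escort protein, went from 10.6 ± 3.56 to 30.3 ± 7.81 (1.45, SE 0.264, adjusted p = 7.29e-05). The synaptic genes Nrxn2 (1.12) and Shank1 (1.11) and the ligand Wnt7b (1.00, adjusted p = 0.000354) rose with the rest.

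Relative to the other genes, 100 rat genes (75 regions) differed in H3K9Ac between VPA vehicle and control under both rescalings, 3 higher and 97 lower. As deposited 18 of them were called, all as higher, for most the opposite direction. The share of higher calls was 100% as deposited, 52.7% after median centring (1823 higher and 1636 lower, 1972 regions) and 3.96% after quantile normalization (4 higher and 97 lower). Among the lower genes, Scn2a1, a neuronal sodium channel, had 7.55 ± 0.688 in vehicle and 8.65 ± 1.09 in controls (SD, n = 3). This is -0.97 relative to the other genes (SE 0.174, adjusted p = 0.0442, inside the gene at chromosome 3, 58321600 to 58325199) and -0.17 as deposited (adjusted p = 0.512). After quantile normalization the cadherin Cdh10 was lower by 0.65, the neuronal GTPase Rit2 by 0.61 (SE 0.0612, adjusted p = 0.0152), the axon guidance factor Sema3a by 0.59 (adjusted p = 0.0442) and the Rac regulator Chn1 by 0.54. As deposited these 4 were higher in vehicle and not called, by 0.16, 0.23, 0.21 and 0.29 (adjusted p = 0.534, 0.377, 0.421 and 0.263). The 3 higher genes were Cyth3 (0.53, adjusted p = 0.0477) and Mafa and Zc3h3, which share a region (0.33, adjusted p = 0.0477) and were named after their values were seen. The 100 became 2864 without vehicle 3, whose summed signal of 161340 lay below the 263090 and 283850 of vehicle 1 and 2. They became 736 without control 1, 3 and 1 without controls 2 and 3, 0 without vehicle 1 or 2, and 309 and 64 without TAK-418 libraries 1 and 3.

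H3K9Ac was called lower in VPA rats given TAK-418 than in those given vehicle at 1605 genes as deposited (1262 regions in all) and higher at 1, B3galt2 (6.87 ± 1.83 against 3.79 ± 0.279, 0.69, adjusted p = 0.0477), a gene singled out after its values were seen. Among the largest decreases, Scap went from 30.3 ± 7.81 to 8.42 ± 3.39 (SD, n = 3; log2 change -1.77, SE 0.264, adjusted p = 1.68e-07) and the LIM-domain regulator Lmo4 from 36.7 ± 11.7 to 12.2 ± 4.57 (-1.53, adjusted p = 2.03e-05). Tab2 went from 85.5 ± 16.7 to 29.8 ± 7.39 (-1.50, SE 0.281, adjusted p = 0.000176). The 1606 calls became 14844 without vehicle 3, 266, 69 and 52 without controls 1, 2 and 3, 13 and 24 without vehicle 1 and 2, and 3 and 22 without TAK-418 libraries 1 and 3.

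Under both rescalings, H3K9Ac differed between TAK-418 and vehicle at 383 rat genes (293 regions), 266 higher and 117 lower with TAK-418; 115 were also called as deposited. Higher calls were 0.0623% of the total as deposited, 53.0% after median centring (1415 higher and 1254 lower) and 70.6% after quantile normalization (293 higher and 122 lower). Scn2a1 rose by 1.04 relative to the other genes (11.9 ± 1.94 against 7.55 ± 0.688, SD, n = 3; SE 0.174, adjusted p = 0.0187). The neuronal membrane glycoprotein Gpm6a rose by 1.02 (11.8 ± 2.73 against 7.53 ± 0.270, SE 0.194, adjusted p = 0.0252, chromosome 16, 39248000 to 39255999) and Dlgap1, a scaffold of the postsynaptic density, by 0.70 (SE 0.101, adjusted p = 0.0149). The catenins Ctnna1 and Ctnnd1 were higher by 0.78 and 0.73. Scap, the kinase Stk39 and Tab2 changed by -1.15, -0.63 and -0.61. The 383 became 1 without vehicle 1 or without TAK-418 library 1, 23 and 169 without vehicle 2 and 3, 247 without TAK-418 library 3, and 621 without control 1.

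Against control, TAK-418-treated VPA rats had no H3K9Ac call: limma gave 0 genes as deposited (1445 at unadjusted p under 0.05) and 0 after median centring and quantile normalization (2865 and 3549). Sepw1, a selenoprotein, had 12.6 ± 0.173 against 5.83 ± 1.11 (SD, n = 3; log2 change 1.01), Cyth3 0.86 and Rsl1d1 0.82 (adjusted p = 0.285 for each), and 99.2% of genes had the higher mean. Ribosomal protein genes were called higher than the other genes as a list under all 3 scalings (69 genes, 53 above the median of all, median 0.44 against 0.36, adjusted p = 0.000302 by camera). Of them 0 were called and 0 adjusted over the list alone (adjusted p = 0.998 with an estimated correlation). The count of 0 became 8629 without vehicle 3, a library outside this comparison that enters the shared estimate of spread. A fit of only the 6 libraries compared called 6188 genes, 6187 of them higher.

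Rat H3K27me3 had no call of single genes as deposited. Limma called 0 of 7816 genes in each comparison, with 0 at unadjusted p under 0.05 in all 3; after median centring and quantile normalization the unadjusted counts were 282 and 431 for vehicle against control, and 444 and 574 for TAK-418 against vehicle. In TAK-418 against control 3 genes were lower under both rescalings. These were the amino acid transporter Slc16a10 (6.22 ± 2.37 against 9.71 ± 4.32, SD, n = 3; log2 change -0.59 after quantile normalization, SE 0.0527, adjusted p = 0.00502), Pkn3 (-0.49, adjusted p = 0.00628) and LOC100125362 (-0.48, adjusted p = 0.00628), the last named after its values were seen.

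As lists, the developmental genes that carry the highest H3K27me3 were called above the other genes in VPA rats with the preset correlation of the test, and not with an estimated correlation. All 8 regions of Hox genes lay above the median of all genes (list median 0.22 against 0.01, adjusted p = 0.00581, and 0.996 with an estimated correlation), among them that of Hoxd10 (35.8 ± 9.13 against 31.4 ± 12.8, SD, n = 3). So did all 58 regions of other developmental transcription factors (0.16, adjusted p = 5.57e-09, and 0.996 with an estimated correlation), among them that of Hand2 (16.4 ± 4.71 against 13.3 ± 4.75). No member passed on its own (0 called and 0 adjusted over the list alone in both lists). The calls with the preset correlation were made under all 3 scalings. With TAK-418 against vehicle, other developmental transcription factors were called lower (58 genes, median 0.000874, mean -0.00497; 3 above the median of all, 0.06, adjusted p = 0.0254) and olfactory receptor genes higher (28 genes, 0.11, 23 above, adjusted p = 0.00826). In both, 0 members were called and 0 adjusted over the list alone (adjusted p = 1 with an estimated correlation). The median and mean of the first list differ in sign, and its call was lost on rescaling. Against control, olfactory receptor genes were again called higher (28 genes, 0 called, 0 adjusted over the list alone, median 0.16; adjusted p = 0.00112, and adjusted p = 0.998 with an estimated correlation). Both olfactory calls held after median centring (adjusted p = 0.0376 and 0.0161) and were lost on quantile normalization (adjusted p = 0.151 and 0.0576).

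For H3K9me3 in rats, 2275 of 4986 genes (1831 regions) were called higher in VPA vehicle than in control libraries and 0 lower. The sulfotransferase Sult1c2 went from 7.84 ± 2.20 to 20.5 ± 4.96 (SD, n = 3; log2 change 1.28, SE 0.373, adjusted p = 0.0175), and Fam111a from 2.99 ± 1.27 to 9.23 ± 5.51 (1.28, SE 0.305, adjusted p = 0.00502). Zcwpw1, a histone methylation reader of meiotic cells, went from 4.09 ± 1.58 to 10.1 ± 1.48 (1.16, SE 0.337, adjusted p = 0.0175). After median centring limma called 6 genes (3 higher and 3 lower), and after quantile normalization 0 (625 at unadjusted p under 0.05). The 2275 became 4236, 1509 and 3695 without TAK-418 libraries 1, 2 and 3, 143, 32 and 22 without controls 1, 2 and 3, 64 without vehicle 1 and 0 without vehicle 2. Control 1 had 7704 called intervals against 15861 and 15533 in controls 2 and 3.

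As lists, the chemosensory families were called above the rest in this H3K9me3 increase, and neither was with an estimated correlation (adjusted p = 0.996). Of 471 regions of olfactory receptor genes 383 rose, and 420 adjusted over the list alone (median 0.57 against 0.40 for all, adjusted p = 2.12e-06), with Olr1119 at 3.25 ± 0.503 against 1.52 ± 0.346 (SD, n = 3; 0.76, SE 0.146, adjusted p = 0.000673). Of 138 regions of vomeronasal receptor genes 113 rose, and 128 adjusted over the list alone (median 0.61, adjusted p = 0.0012), with Vom1r80 at 4.05 ± 0.240 against 1.88 ± 0.305 (0.81, SE 0.212, adjusted p = 0.0121). Other developmental transcription factors were called below the rest (50 genes, 6 higher, 0 adjusted over the list alone; median 0.26, adjusted p = 1.07e-06, and 0.996 with an estimated correlation), among them the heart regulator Nkx2-5 (0.55, adjusted p = 0.0343). So were imprinted genes (13 genes, 2 higher, 0 adjusted over the list alone; median 0.27, adjusted p = 8.33e-05, and 0.996 with an estimated correlation), with the Notch-related Dlk1 at 0.26 (adjusted p = 0.0433) and Ndn at 0.46 (adjusted p = 0.0486). The call of imprinted genes was also lost on median centring.

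For TAK-418 against vehicle in rat H3K9me3, limma called 0 genes as deposited, after median centring and after quantile normalization (14, 113 and 75 at unadjusted p under 0.05). Hox genes (7 genes, median -0.16 against -0.04, adjusted p = 0.001), other developmental transcription factors (50 genes, -0.09, adjusted p = 0.000117) and imprinted genes (13 genes, -0.28, adjusted p = 0.000837) were called lower as lists. Of their members 0 were called and 0 adjusted over the list alone (adjusted p = 1 with an estimated correlation). Imprinted Plagl1 had 4.36 ± 0.794 against 6.99 ± 2.09 (SD, n = 3; -0.56), Magel2 stood at -0.53 and Mest at -0.50. Without TAK-418 library 1 the count was 6.

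Against control, 903 rat genes had higher H3K9me3 with TAK-418 (763 regions), and 0 lower. Fam111a (8.15 ± 2.74 against 2.99 ± 1.27, SD, n = 3; 1.21, adjusted p = 0.00564) and Zcwpw1 (1.15, adjusted p = 0.0179) were again among the largest. Olfactory receptor genes (471, of which 185 rose, and 368 adjusted over the list alone; median 0.52 against 0.36, adjusted p = 2.24e-06) and vomeronasal receptor genes (138, of which 41 rose, and 110 adjusted over the list alone; 0.55, adjusted p = 0.0185) were called higher, and not with an estimated correlation (adjusted p = 0.998). Hox genes (7, median 0.12, adjusted p = 0.00011), other developmental transcription factors (50, 0.17, adjusted p = 1.51e-14) and imprinted genes (13, 0.11, adjusted p = 1.1e-10) were called lower than the rest, and not with an estimated correlation (adjusted p = 0.998). Of their members 0 were called and 0 adjusted over the list alone. The calls with the preset correlation were made under all 3 scalings. Median centring left 37 genes (10 higher and 27 lower, or 27.0% higher) and quantile normalization 0 (721 at unadjusted p under 0.05). Without control 1, 2 or 3 the 903 became 178, 64 and 2, without vehicle 1 or 3 they became 152 and 331, and without TAK-418 library 1 or 3 they became 81 and 3748.

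In mice, vehicle against control gave no H3K4me3 call as deposited, although only 0.0917% of genes had the higher mean in vehicle: limma called 0 of 17446 genes (7856 at unadjusted p under 0.05; smallest adjusted p = 0.11). The smallest p belonged to Zfp931, a zinc finger gene (7.67 ± 3.55 in vehicle against 19.2 ± 9.83 in controls, SD, n = 3; log2 change -1.20, SE 0.282) and Tnfsf10, the death ligand TRAIL (4.34 ± 1.09 against 9.53 ± 3.98, -0.94). Kdm1a had 14.4 ± 6.81 in controls, 8.23 ± 0.554 in vehicle and 10.1 ± 1.18 with TAK-418. Synaptic genes were called lower than the other genes as a list (29 genes, 24 below the median of all, list median -0.59 against -0.49, adjusted p = 0.0418, and 0.991 with an estimated correlation). So were glutamate receptor genes (25 genes, -0.61, adjusted p = 0.0442, and 0.991 with an estimated correlation), in both cases under all 3 scalings with the preset correlation. The kainate receptor Grik2 had 12.2 ± 2.42 against 22.0 ± 9.41 (-0.75), at an adjusted p of 0.11. Zinc finger genes (Zfp and Znf) were called higher than the rest (296 genes, -0.45, adjusted p = 0.0442, and 0.991 with an estimated correlation). No member of these lists was called (0), and 0, 0 and 1 were called adjusted over the list alone. Control 1, with a summed signal of 308210, stood apart from controls 2 and 3; the count became 15 without it and 12959 without control 3.

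A single mouse gene, Ccdc22 of an endosomal sorting complex, was called under both rescalings as higher with poly I:C (chromosome X, 7607400 to 7612599). It had 6.07 ± 0.782 against 6.37 ± 2.05 (SD, n = 3), which is -0.03 as deposited and 0.43 after quantile normalization (SE 0.0447, adjusted p = 0.0364).

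In poly I:C mice, H3K4me3 differed between TAK-418 and vehicle at 107 genes (68 regions) under both rescalings, 52 higher and 55 lower with TAK-418, while limma called 0 as deposited (75 at unadjusted p under 0.05). The Wnt receptor Fzd5 rose by 0.55 relative to the other genes (12.0 ± 1.36 against 7.44 ± 1.58, SD, n = 3; SE 0.0663, adjusted p = 0.0178, chromosome 1, 64730800 to 64741599). The secreted Wnt antagonist Frzb rose by 0.33 (9.84 ± 1.05 against 7.11 ± 1.13, SE 0.0583, adjusted p = 0.0423). Tceal6 (6.10 ± 0.549 against 8.27 ± 1.26, SE 0.0549, adjusted p = 0.0122) changed by -0.53 and Ccdc22 (4.62 ± 0.628 against 6.07 ± 0.782, SE 0.0447, adjusted p = 0.00864) by -0.50. Both lie on chromosome X, as does Armcx5 (-0.46). The 107 became 2685 without vehicle 1, 0 without vehicle 3 or TAK-418 library 3, and between 3 and 14 without any other single library.

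As lists, neural progenitor genes were called higher with TAK-418 in mouse H3K4me3 (14 genes, 12 above the median of all, list median 0.23 against 0.13, adjusted p = 0.00916), a call made under all 3 scalings but not with an estimated correlation (adjusted p = 1). The neurogenic factor Neurog2 had 2.45 ± 0.103 against 1.80 ± 0.11 (SD, n = 3; 0.30) and Sox2 7.69 ± 1.18 against 5.76 ± 1.17 (0.37) (adjusted p = 0.999 for each). Excitatory neuron markers (16 genes, 0.19, adjusted p = 0.0406) and Wnt ligand genes (15 genes, 0.15, adjusted p = 0.0396), with Wnt5a at 0.38, were called higher (adjusted p = 1 with an estimated correlation). Zinc finger genes (Zfp and Znf) were called lower (296 genes, 0.07, adjusted p = 0.0327). Called higher as well were other developmental transcription factors, although their median of 0.12 lay below that of all genes (36 genes; adjusted p = 0.0122). In each of the 5 lists 0 members were called and 0 adjusted over the list alone, with an adjusted p of 1 at an estimated correlation. The count of 0 became 268 without control 1.

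Against control, mouse H3K4me3 with TAK-418 was lower at 1 gene under every scaling. This was the zinc finger gene model Gm14418 (4.79 ± 0.444 against 14.8 ± 6.11, SD, n = 3; -1.38, SE 0.267, adjusted p = 0.00423), which the naming rule leaves out and which was chosen after its values were seen. Other developmental transcription factors (36 genes, 35 above the median of all, list median -0.17 against -0.37, adjusted p = 2.58e-05), Wnt ligand genes (15 genes, -0.23, adjusted p = 0.0128) and neural progenitor genes (14 genes, -0.32, adjusted p = 0.0261) were called above the other genes, and not with an estimated correlation (adjusted p = 0.997). Of their members 0 were called and 0 adjusted over the list alone. The count of 1 became 4 without control 1, and 0 without vehicle 3, without any 1 of the TAK-418 libraries, with the highest signal in place of the mean and with only the 6 libraries compared.

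For H3K9Ac in mice, 11204 of 16663 genes were called lower in poly I:C vehicle than in control libraries as deposited (5524 regions in all) and 1 higher, Zfp934 (5.39 ± 0.993 against 3.74 ± 1.49, 0.46, adjusted p = 0.0457), named after its values were seen. The kinase Map4k2 went from 13.0 ± 2.28 to 6.62 ± 2.02 (SD, n = 3; log2 change -0.91, SE 0.284, adjusted p = 0.0289, chromosome 19, 6329200 to 6357399). With the same adjusted p, Dot1l, the H3K79 methyltransferase, went from 13.2 ± 3.07 to 6.84 ± 2.56 (-0.89, SE 0.285). The glutamate receptor subunit Grin2c fell from 8.64 ± 1.71 to 4.82 ± 1.47 (-0.75) and the synaptic gene Nrxn2 from 9.92 ± 2.15 to 5.50 ± 1.56 (-0.76; adjusted p = 0.0289 for each). After rescaling limma called 0 genes (1176 and 780 at unadjusted p under 0.05). The count became 0 without control 1, control 2, vehicle 2 or vehicle 3.

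As lists, interferon and inflammatory genes were called lower than the rest in mouse H3K9Ac with poly I:C (16 genes, 14 lower, 15 adjusted over the list alone; list median -0.59 against -0.56, adjusted p = 0.0442, and 0.991 with an estimated correlation). Zinc finger genes (Zfp and Znf) were called higher than the rest under all 3 scalings (286 genes, 1 higher and 122 lower, 0 adjusted over the list alone; -0.49, adjusted p = 0.000239, and 0.991 with an estimated correlation). With TAK-418 against vehicle, limma called 0 genes as deposited, median centred and quantile normalized (5, 272 and 410 at unadjusted p under 0.05). In that comparison Wnt ligand genes were called higher under all 3 scalings (13 genes, median 0.10 against 0.05, adjusted p = 0.00916, and 1 with an estimated correlation). Zinc finger genes (Zfp and Znf) were called lower, with a median and mean that differ in sign (286 genes, median 0.000386, mean -0.0121, adjusted p = 0.0171). In both lists 0 members were called and 0 adjusted over the list alone (adjusted p = 1 with an estimated correlation).

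TAK-418-treated poly I:C mice had lower H3K9Ac than controls in nearly all genes without any passing: limma called 0 (13031 at unadjusted p under 0.05; smallest adjusted p = 0.0522). After median centring and quantile normalization limma called 0 as well (727 and 212 at unadjusted p under 0.05). Gon4l had 3.88 ± 0.717 against 7.75 ± 2.13 (SD, n = 3; log2 change -0.83). Ribosomal protein genes were called lower than the rest under all 3 scalings (70 genes, 0 called, 57 adjusted over the list alone; -0.58 against -0.53, adjusted p = 0.0478, and 0.997 with an estimated correlation). So were, as deposited, vascular cell markers (6 genes, 6 adjusted over the list alone; -0.58, adjusted p = 0.0478) and interferon and inflammatory genes (16 genes, 16 adjusted over the list alone; -0.55, adjusted p = 0.0478), neither with an estimated correlation (adjusted p = 0.997). Zinc finger genes (Zfp and Znf) were called higher than the rest (286 genes, 0 adjusted over the list alone; -0.50, adjusted p = 0.0472, and 0.997 with an estimated correlation). The count became 16150 without control 3, 11794 without vehicle 2, 11410 without trend and robust, 11303 with a pseudocount of 4 and 14932 with the replicate block, all lower.

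Mouse H3K27me3 had no call as deposited in any comparison: limma gave 0 of 7732 genes for vehicle against control, TAK-418 against vehicle and TAK-418 against control (0, 73 and 19 at unadjusted p under 0.05). With TAK-418 every tested gene had a lower mean than in vehicle, the smallest p being those of the growth factor Fgf16 (log2 change -0.70), the germ cell gene Boll (-0.83) and Fbn2, a fibrillin of elastic fibres (-0.65; adjusted p = 0.314 for each). Against control, Fbn2 had 2.61 ± 0.514 against 4.51 ± 0.488 (SD, n = 3; -0.62), at an adjusted p of 0.368. Vehicle 3 of this mark had 1916 called intervals against 13596 and 10817 in vehicle 1 and 2; without it the TAK-418 against vehicle count became 7732, all tested genes, and the TAK-418 against control count 1. A fit of only the 6 libraries compared called 5912 genes for TAK-418 against control, all lower.

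Other developmental transcription factors were called lower than the rest in mouse H3K27me3 with poly I:C (61 genes, median 0.02 against 0.05, adjusted p = 0.000131), a call lost on rescaling (adjusted p = 0.991 with an estimated correlation). With TAK-418 against vehicle the same list was called higher as deposited (adjusted p = 1.56e-07, and 1 with an estimated correlation) although its median of -0.57 lay below the -0.46 of all genes and all 61 members were below that median, and the call turned to lower on median centring. Excitatory neuron markers (14 genes, -0.50, adjusted p = 0.00411) and oligodendrocyte markers (11 genes, -0.45, adjusted p = 0.0396) were called higher and zinc finger genes (Zfp and Znf) lower (51 genes, -0.41, adjusted p = 0.0437), none with an estimated correlation (adjusted p = 1). For the first and the last, median and call differ in side. Against control, excitatory neuron markers were called higher with a median of -0.46 against -0.40 (14 genes; adjusted p = 0.041, and adjusted p = 0.997 with an estimated correlation). In these lists 0 members were called and 0 adjusted over the list alone. Vehicle 3 enters each comparison with vehicle.

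Mouse H3K9me3 rested on libraries of unequal strength. Vehicle 1 and 2 and TAK-418 library 2 had 446, 251 and 284 called intervals, while the other 6 libraries had between 4460 and 32258. Limma called 0 of 4184 genes in all 3 comparisons (6, 0 and 0 at unadjusted p under 0.05 as deposited; 452, 124 and 44 median centred; 734, 393 and 36 quantile normalized).

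As lists in mouse H3K9me3, olfactory receptor genes (394 genes, median -0.52 against -0.41 for all, adjusted p = 1.24e-06) and vomeronasal receptor genes (181 genes, -0.59, adjusted p = 2.64e-08) were called lower with poly I:C, and not with an estimated correlation (adjusted p = 0.991). The other developmental transcription factors (all 49 above the median of all, -0.18, adjusted p = 1.31e-13) and imprinted genes (11 genes, -0.17, adjusted p = 2.64e-08) were called higher than the rest (0.991 with an estimated correlation). So were zinc finger genes (Zfp and Znf) (68 genes, adjusted p = 0.0442) although their median of -0.45 lay below that of all genes (0.991 with an estimated correlation). With TAK-418 against vehicle, olfactory receptor genes (0.25 against 0.17, adjusted p = 0.0002) and vomeronasal receptor genes (0.26, adjusted p = 0.000345) were called higher. Other developmental transcription factors (0.04, adjusted p = 2.65e-08) and imprinted genes (-0.04, adjusted p = 1.03e-07) were called lower (adjusted p = 1 with an estimated correlation for all 4). Against control, vomeronasal receptor genes were called lower (-0.32 against -0.22, adjusted p = 0.00763) and other developmental transcription factors higher (-0.15, adjusted p = 0.00763; adjusted p = 0.997 with an estimated correlation for both). In each of these lists 0 members were called and 0 adjusted over the list alone. The 3 libraries with few intervals belong to the vehicle and TAK-418 groups of these comparisons.

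Lists that passed in no comparison of either species, with their smallest adjusted p, were inhibitory neuron markers (0.0768 in rats and 0.114 in mice), astrocyte markers (0.164 and 0.153), oligodendrocyte precursor markers (0.164 and 0.298), microglia markers (0.172 and 0.224) and choroid plexus markers (0.21 and 0.15). So were immediate early genes (0.096 and 0.295), circadian clock genes (0.221 and 0.631), autism risk genes (0.218 and 0.176), LSD1 complex and H3K4 methylation enzymes (0.144 and 0.386), HDAC and sirtuin genes (0.177 and 0.112) and GABA receptor genes (0.515 and 0.0893). Cholesterol synthesis genes (0.13 and 0.214), respiratory chain genes (0.177 and 0.298), clustered protocadherins (0.505 and 0.952) and genes of other organs (0.413 and 0.386) did not pass either, nor did red blood cell genes, tested in mice only (0.603). In all, 6, 5 and 10 of 99 list tests passed in rats for vehicle against control, TAK-418 against vehicle and TAK-418 against control, and 11, 15 and 10 of 87 in mice, and with an estimated correlation 0 passed in each.

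The changes of rat H3K9Ac with VPA and with TAK-418 were inversely related across genes. Across 15368 genes, which are not independent replicates, the changes of vehicle against control and of TAK-418 against vehicle correlated at r = -0.781 (Spearman rho -0.758). This lies inside the 95% range from -0.883 to 0.558 of unchanged simulated groups that share the vehicle libraries (mean -0.475). The covariance of -0.0302 lay outside the simulated range of -0.0143 to 0.00152 (mean -0.00402, difference -0.0262), also after quantile normalization (-0.0153 against -0.013 to 0.00109). Genes called higher in vehicle and lower with TAK-418 numbered 1605 as deposited, 311 after median centring and 0 after quantile normalization (1550, 149 and 0.0318 if the limma calls were independent). Genes called lower and then higher numbered 0, 914 and 52 (0, 151 and 1.85), among the 52 Scn2a1 and Cdh10. Both calls use the same vehicle libraries, and the number shared without any change was not simulated.

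In mouse H3K4me3 the same correlation was r = -0.611 (Spearman rho -0.598; simulated mean -0.443, range -0.913 to 0.573), and the covariance of -0.0113 lay just outside its simulated range of -0.0105 to 0.00215 (difference -0.00785; after quantile normalization -0.0126 against -0.00778 to 0.00115). Ccdc22 was the 1 gene called in both after quantile normalization. The other 6 correlations lay within the simulated range, as did their covariances: -0.217 for rat H3K4me3, -0.254 for rat H3K27me3, -0.409 for rat H3K9me3, -0.64 for mouse H3K9Ac, -0.2 for mouse H3K27me3 and -0.917 for mouse H3K9me3. Their sign turned in rat H3K27me3 (0.0994 without control 3), rat H3K9me3 (0.0592 without TAK-418 library 2) and mouse H3K27me3 (0.371 without control 1, 0.00126 without vehicle 2).

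**Figure D4:**
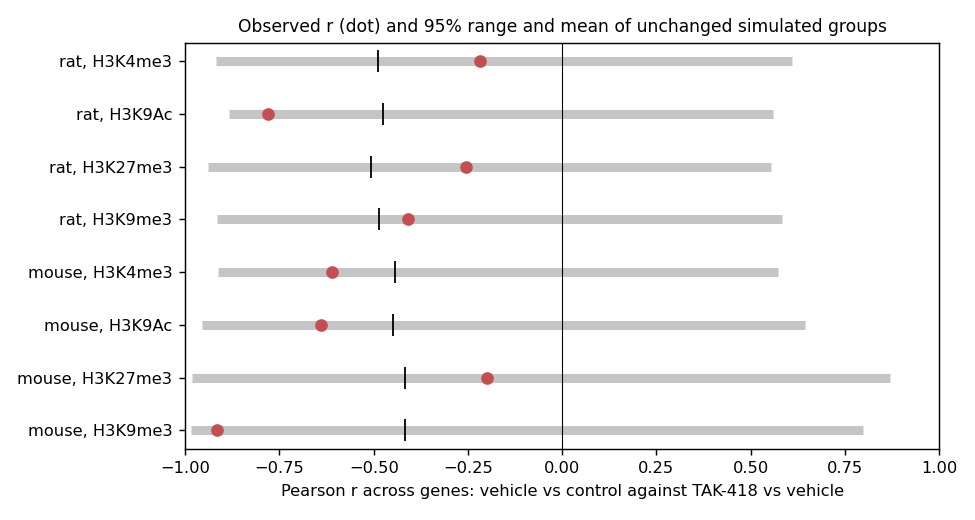
Pearson r across genes between the log2 change of vehicle against control and that of TAK-418 against vehicle (x axis, from -1 to 1) for each mark and species (y axis); dots are the observed values, bars the 95% range and ticks the mean of 100 simulations of unchanged groups. All 8 dots lie inside their bars, from -0.917 in mouse H3K9me3 to -0.2 in mouse H3K27me3.

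Some genes were called in H3K4me3 together with another mark as deposited, and 0 under both rescalings. As deposited, 228 rat genes rose with VPA in both H3K4me3 and H3K9Ac and 7 in both H3K4me3 and H3K9me3; with TAK-418 against vehicle 2 were called in H3K4me3 and H3K9Ac without regard to direction (all 21 H3K4me3 calls were higher and all H3K9Ac calls but 1 lower), and with TAK-418 against control 107 were called in H3K4me3 and H3K9me3. With VPA 96.5% of tested genes rose in H3K9Ac, and with TAK-418 against control 85.8% changed in H3K4me3, so most genes of the smaller set would be shared without any link. Zbtb7c is named in both active marks. An effect that passed in rats and not in mice, or the reverse, is not shown to differ between the models, since that difference was not tested gene by gene.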

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

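The tests in this part were chosen after the results were seen, except the counts of genes with each library left out, which were planned. The test of the median change with 1 library left out was added after the count under the same explanation was known.

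In 5 pairs of mark and group, every rat library exceeded the mean summed signal of its controls and every mouse library fell below it. This was not so for H3K27me3 in either group or for H3K9me3 of vehicle. The difference between models was not tested. H3K4me3 of vehicle libraries was 1.34 ± 0.0443 times the control mean in rats (SD, n = 3; range 1.29 to 1.38) and 0.655 ± 0.0646 in mice (0.597 to 0.724), and with TAK-418 1.58 ± 0.324 (1.20 to 1.77) and 0.706 ± 0.06 (0.637 to 0.748). H3K9Ac of vehicle libraries was 2.01 ± 0.557 (1.37 to 2.41) in rats and 0.642 ± 0.114 (0.516 to 0.739) in mice, and with TAK-418 1.31 ± 0.206 (lowest 1.09) and 0.657 ± 0.113 (0.527 to 0.732). H3K9me3 with TAK-418 was 1.32 ± 0.239 (1.09 to 1.56) in rats and 0.825 ± 0.182 (0.630 to 0.990) in mice. Sequencing depth and batch of each library are unknown here.

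For the higher H3K9Ac of VPA rats, a scaling or depth factor of whole libraries would move regions with and without the mark alike. At control levels of 2 to 3, 970 regions with the mark changed by 0.621 ± 0.3616 and 560 without it by 0.5734 ± 0.3656 (log2, SD, n = 3). The difference of 0.04756 was under the bound of 0.1 set for this test, which is consistent with such a factor, while in the H3K4me3 libraries of rats the same difference was above it by less than its SD (0.1324 ± 0.07146 in vehicle and 0.1878 ± 0.1002 with TAK-418) and in those of mice below it (0.007354 and 0.02593). One library did not make the change, as the fewest genes called with any 1 left out was 13010 and the weakest median change 0.734 (up to 1.11; 0.88 with all). VPA exposure stays open beside the scaling factor.

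For the lower H3K9Ac of poly I:C mice, 100 regions with the mark changed by -0.2625 and 1462 without it by -0.2668, a difference of 0.004294. That change was under the bound of 0.3 needed to decide on a scaling or depth factor of whole libraries. By the count, 1 library may make the result, since the fewest genes called with any 1 left out was 0. By the median change it does not, since the weakest was -0.421 (down to -0.708; -0.557 with all). Poly I:C exposure was not separated from scaling.

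The X-linked decrease of H3K4me3 with TAK-418 in poly I:C mice was picked among 24 such contrasts: 67.2% of 533 X-linked regions were lower, and their median of -0.082 lay -0.0976 from that of 11906 autosomal regions. Autosomal regions matched for length, CpG islands and level changed by -0.0959, a difference of 0.0139, so the make-up of the regions is likely to account for it. Leaving out 1 library left at least -0.0815 (down to -0.115), which speaks against 1 library as the source. The real split was the 1 of 10 as large (next 0.0717), too few splits for a share under 0.05. No action of TAK-418 on the X chromosome was separated from the make-up of the regions.

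Each comparison allows only 10 splits of its 6 libraries, too few for a share under 0.05. Genes called in the real split and the most in any other are given for vehicle against control, TAK-418 against vehicle and TAK-418 against control in turn. In rats they were 250 and 12, 21 and 41, and 13113 and 11199 for H3K4me3, 14835 and 0, 1606 and 14326, and 0 and 0 for H3K9Ac, 0 and 0, 0 and 0, and 0 and 7622 for H3K27me3, and 2275 and 0, 0 and 1189, and 903 and 2 for H3K9me3. In mice they were 0 and 0, 0 and 0, and 1 and 0 for H3K4me3, 11205 and 0, 0 and 0, and 0 and 0 for H3K9Ac, 0 and 7225, 0 and 7485, and 0 and 0 for H3K27me3, and 0 and 36, 0 and 3985, and 0 and 0 for H3K9me3. The relative changes gave 100 and 0 and 383 and 0 in rat H3K9Ac and 107 and 0 in mouse H3K4me3. A split that called several times the real count points to a structure of the samples, as with 14326 against 1606 in rat H3K9Ac and with 7622, 1189, 7225, 7485 and 3985 against 0. The source of that structure was not tested. Splits as large, the real one included, numbered 2 for rat H3K4me3 and rat H3K9Ac in TAK-418 against vehicle, 1 in every other comparison with a call, and 10 where the real split called 0.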

How the results depend on the processing

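The relative changes and their alternatives, the highest signal, the region strongest for the mark, regions inside the gene only, regions in place of genes and the replicate block with a rescaling were chosen after the data were seen, and the other alternatives before. Results that answer a comparison stayed within 1.5 times or on the same side in 642 alternatives, moved in 249 and reversed in 5. The 642 include counts of 0 that stayed 0, so the tally does not show how stable called counts were. For single named genes and percentiles, 21 stayed, 14 moved and 123 of the genes no longer passed, and none reversed. The increase of rat H3K9Ac with VPA was called as deposited under every setting run, at the fewest at 7411 genes with regions inside the gene only and 13010 with 1 library left out. Values are numbers of genes called unless stated. Depth is unknown, so what limits precision was not determined.

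Median centring gave for vehicle against control 0 in rat H3K4me3 and mouse H3K9Ac, 3459 in rat H3K9Ac, 6 in rat H3K9me3 and 1 in mouse H3K4me3, for TAK-418 against vehicle 0 in rat H3K4me3, 2669 in rat H3K9Ac, 196 in mouse H3K4me3 and 2 in mouse H3K27me3, and for TAK-418 against control 0 in rat H3K4me3, 11 in rat H3K27me3, 37 in rat H3K9me3 and 2 in mouse H3K4me3. Passing lists numbered 17 for rat vehicle against control. Quantile normalization gave for vehicle against control 0 in rat H3K4me3, rat H3K9me3 and mouse H3K9Ac, 101 in rat H3K9Ac and 1 in mouse H3K4me3, for TAK-418 against vehicle 0 in rat H3K4me3, 415 in rat H3K9Ac, 1 in rat H3K27me3 and 141 in mouse H3K4me3, and for TAK-418 against control 0 in rat H3K4me3 and rat H3K9me3, 4 in rat H3K27me3 and 2 in mouse H3K4me3. Passing lists numbered 12 for rat vehicle against control and 8 for mouse TAK-418 against vehicle. Rescaling takes out any change that all genes share, so by its construction it removes the shared part of these counts. It does not show whether that part came from the tissue or the scaling.

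Limma without trend and robust estimation gave for vehicle against control 1225 in rat H3K4me3 and 1 in mouse H3K4me3, for TAK-418 against vehicle 0 in rat H3K4me3 and 6342 in rat H3K9Ac, and for TAK-418 against control 0 in rat H3K9me3 and 11410 in mouse H3K9Ac, with relative changes at 10 for mouse H3K4me3 TAK-418 against vehicle. A pseudocount of 4 gave for vehicle against control 80 in rat H3K4me3, for TAK-418 against vehicle 36 in rat H3K4me3, and for TAK-418 against control 448 in rat H3K9me3 and 11303 in mouse H3K9Ac. Testing without the interval filter gave for vehicle against control 2 in rat H3K4me3 (both lower), 6 in rat H3K27me3, 636 in rat H3K9me3, 5 in mouse H3K4me3 and 1 in mouse H3K27me3, for TAK-418 against vehicle 9 in rat H3K4me3, 949 in rat H3K9Ac, 6 in rat H3K27me3, 22 in rat H3K9me3, 4 in mouse H3K9Ac and 176 in mouse H3K27me3, and for TAK-418 against control 11 in rat H3K9Ac, 7 in rat H3K27me3, 3 in mouse H3K4me3, 111 in mouse H3K9Ac and 91 in mouse H3K27me3, with relative changes at 0 for rat H3K9Ac vehicle against control, 150 for rat H3K9Ac TAK-418 against vehicle and 8 for mouse H3K4me3 TAK-418 against vehicle. Passing lists numbered 27 for rat vehicle against control and 13 for rat TAK-418 against vehicle. The correlation of rat H3K4me3 changes turned to 0.113. Testing the upper 50% by mean level gave for vehicle against control 125 in rat H3K4me3, 1207 in rat H3K9me3, 2 in mouse H3K4me3 and 1 in mouse H3K27me3 and mouse H3K9me3, for TAK-418 against vehicle 0 in rat H3K4me3, 3579 in rat H3K9Ac, 10 in rat H3K9me3 and 6 in mouse H3K27me3, and for TAK-418 against control 8588 in rat H3K4me3, 10 in mouse H3K9Ac and 3 in mouse H3K27me3, with relative changes at 62 for rat H3K9Ac vehicle against control and 233 for mouse H3K4me3 TAK-418 against vehicle. Fitting only the 6 libraries compared gave for vehicle against control 6658 in rat H3K4me3 and 4337 in rat H3K9me3, for TAK-418 against vehicle 33 in rat H3K4me3, 17 in rat H3K9Ac and 88 in mouse H3K4me3, and for TAK-418 against control 6188 in rat H3K9Ac, 134 in rat H3K9me3, 0 in mouse H3K4me3 and 5912 in mouse H3K27me3. The highest signal in place of the mean gave for vehicle against control 3 in rat H3K4me3, 805 in rat H3K9me3 and 2 in mouse H3K9Ac, for TAK-418 against vehicle 0 in rat H3K4me3 and 11101 in rat H3K9Ac, and for TAK-418 against control 224 in rat H3K9me3 and 0 in mouse H3K4me3, with relative changes at 10 for rat H3K9Ac vehicle against control, 630 for rat H3K9Ac TAK-418 against vehicle and 713 for mouse H3K4me3 TAK-418 against vehicle. Counting regions in place of genes gave for vehicle against control 14664 in rat H3K9me3, for TAK-418 against vehicle 32 in rat H3K4me3, and for TAK-418 against control 10309 in rat H3K9me3, with relative changes at 64 for rat H3K9Ac vehicle against control, 596 for rat H3K9Ac TAK-418 against vehicle and 33 for mouse H3K4me3 TAK-418 against vehicle. Keeping regions inside the gene only gave for vehicle against control 100 in rat H3K4me3, 7411 in rat H3K9Ac, 893 in rat H3K9me3 and 4840 in mouse H3K9Ac, for TAK-418 against vehicle 10 in rat H3K4me3, and for TAK-418 against control 6045 in rat H3K4me3 and 538 in rat H3K9me3, with relative changes at 41 for rat H3K9Ac vehicle against control and 20 for mouse H3K4me3 TAK-418 against vehicle. Taking the first region listed for a gene gave for TAK-418 against vehicle 234 in rat H3K9Ac, and for TAK-418 against control 1554 in rat H3K9me3, with relative changes at 196 for rat H3K9Ac TAK-418 against vehicle. Taking the region strongest for the mark gave for vehicle against control 3990 in rat H3K9me3, and for TAK-418 against control 2241 in rat H3K9me3. With an estimated inter-gene correlation, 0 lists passed in either species for vehicle against control or TAK-418 against vehicle. With the level divided by the length of the region in kb, fewer list levels over the marks stood at percentile 80 or above. They numbered 1 in rat and 7 in mouse. A pseudocount of 0.25 moved no such result. The upper 50% and the interval filter change how many genes are tested, and the fit on 6 libraries has fewer samples for the spread. For the other settings the cause was not tested. The planned gene window was not run, since the tables hold 1 value per merged region, and neither was a correction by pooled input.

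Libraries that share a replicate number were not paired: in 1 of 24 checks (4 marks, 3 comparisons, 2 species) were all 3 same-number correlations of deviations above 0.1, over a range from -0.662 to 0.775, and in that check every library correlated best with its own number (mouse H3K27me3, TAK-418 against control). The replicate block gave for vehicle against control 3 in rat H3K4me3, 48 in rat H3K9me3 and 4 in mouse H3K4me3, for TAK-418 against vehicle 4 in rat H3K4me3 and 10420 in rat H3K9Ac, and for TAK-418 against control 4 in rat H3K9Ac, 159 in rat H3K9me3 and 14932 in mouse H3K9Ac, with relative changes at 4 for rat H3K9Ac vehicle against control and 147 for rat H3K9Ac TAK-418 against vehicle. The replicate block with median centring gave for vehicle against control 0 in rat H3K4me3 and mouse H3K9Ac, 2395 in rat H3K9Ac, 9 in rat H3K9me3, 8 in mouse H3K4me3 and 108 in mouse H3K9me3, for TAK-418 against vehicle 0 in rat H3K4me3, 611 in mouse H3K4me3, 2 in mouse H3K27me3 and 36 in mouse H3K9me3, and for TAK-418 against control 0 in rat H3K4me3, 8 in rat H3K27me3, 88 in rat H3K9me3 and 7 in mouse H3K4me3. The replicate block with quantile normalization gave for vehicle against control 0 in rat H3K4me3 and mouse H3K9Ac, 4 in rat H3K9Ac, 1 in rat H3K9me3 and 2 in mouse H3K4me3, for TAK-418 against vehicle 0 in rat H3K4me3, 154 in rat H3K9Ac and 183 in mouse H3K4me3, and for TAK-418 against control 0 in rat H3K4me3 and rat H3K9me3, 3 in rat H3K27me3 and 2 in mouse H3K4me3.

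Leaving out each library in turn moved the counts of genes, given as lowest to highest. In rats, for vehicle against control, TAK-418 against vehicle and TAK-418 against control in turn, H3K4me3 gave 2 to 8365, 0 to 509 and 3558 to 14810. H3K9Ac gave 13010 to 15303, 3 to 14844 and 0 to 8629. H3K9me3 gave 0 to 4236, 0 to 6 and 2 to 3748. In mice, H3K4me3 gave 0 to 12959, 0 to 268 and 0 to 4 in this order. H3K9Ac gave 0 to 15714 for vehicle and 0 to 16150 for TAK-418, both against control. H3K27me3 gave 0 to 7732 for TAK-418 against vehicle and 0 to 1 for TAK-418 against control. All other counts stayed at 0. The relative changes ranged from 0 to 2685 in mouse H3K4me3 TAK-418 against vehicle, 1 to 621 in rat H3K9Ac TAK-418 against vehicle and 0 to 2864 in rat H3K9Ac vehicle against control. The correlations for H3K4me3, H3K9Ac, H3K27me3 and H3K9me3 in turn ranged from -0.4 to -0.0701, -0.834 to -0.733, -0.493 to 0.0994 and -0.716 to 0.0592 in rats. In mice they ranged from -0.757 to -0.477, -0.787 to -0.206, -0.933 to 0.371 and -0.956 to -0.76. Lists passing ranged from 3 to 10 in rats and 6 to 14 in mice for vehicle against control, and from 0 to 7 and 8 to 14 for TAK-418 against vehicle. A group left with 2 libraries was assumed to vary like the others, and the cause was not tested.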

Other observations

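The tests in this part were chosen after the results were seen, and the rule by which a negative correlation counts against shared changes was added after the correlations were known.

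The relative changes of active marks fell on regions of different make-up, and the shares given here were noticed after the data were seen. Of the regions with relatively lower H3K9Ac in VPA rats 38.4% held a CpG island (28 of 73; median length 6799 bp), against 82.4% of those not called (7920 of 9612; 10999 bp). With TAK-418 the regions that were higher held one in 27.1% (52 of 192), and the lower ones in 97.0% (98 of 101), both with a median length of 7999 bp. In poly I:C mice treated with TAK-418, 97.0% of the regions higher in H3K4me3 held a CpG island (32 of 33; 14599 bp) and 60.0% of the lower ones (21 of 35; 6599 bp), against 85.5% of the rest (8268 of 9671; 13199 bp). Of those lower regions 7 were X-linked (20.0%), against 4.22% of regions not called (408 of 9671) and 0 of the 33 higher. Autosomal regions matched to all X-linked ones for length, CpG islands and level changed by -0.0959, against -0.082 on the X chromosome. Y-linked regions were kept only where an H3K4me3 interval had been called in all 9 mouse libraries. The mean signal over the 4 regions so chosen ranged from 8.41 to 20.6 per library.

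Relative changes shared by both exposure models were tested as a hypothesis on genes of the same symbol after quantile normalization, beside 100 pairs of splits. Genes are not independent replicates, and share p-values were adjusted over the 8 tests. For vehicle against control, r was -0.414 in H3K4me3 (Spearman rho -0.415; 12095 genes; 1 pair as large, adjusted permutation p = 0.04; highest other 0.4) and -0.519 in H3K9me3 (rho -0.518; 807 genes; 1 pair, adjusted permutation p = 0.04; highest other 0.406). Shared changes would give a positive r, but this reading was set after the values were known. The latter value rests in part on mouse libraries with few intervals. It was -0.515 in H3K9Ac (rho -0.559; 11759 genes; 8 pairs, adjusted permutation p = 0.213; highest other 0.564) and -0.0947 in H3K27me3 (rho -0.112; 4280 genes; 59 pairs, adjusted permutation p = 0.62; highest other 0.352), which leaves both undecided. For TAK-418 against vehicle, values of -0.0566, -0.202, 0.198 and 0.171 in H3K4me3, H3K9Ac, H3K27me3 and H3K9me3 (rho -0.054, -0.214, 0.144 and 0.111) came with 62, 30, 26 and 46 pairs as large, adjusted permutation p of 0.62, 0.48, 0.48 and 0.613, and highest other values of 0.245, 0.511, 0.328 and 0.459, which decides none of them.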
